A study of Caenorhabditis elegans with 2 samples.

How the data were processed

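Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole Caenorhabditis elegans larvae of the L3 stage. The worms came from strain OP212, which per the labels carries a transgene named ddEx58 in an unc-119(ed3) background, and the target was CEH-82 joined to enhanced green fluorescent protein (eGFP). There were 2 samples in 1 group, and the labels call them biological replicates 1 and 2. No other condition was analysed here, so no comparison between conditions was made.

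Per the file headers and the text files deposited with the peak lists, the authors made 3 kinds of list, each on the genome builds ce11 and ce10. The first is a list of reproducible peaks past an irreproducible discovery rate threshold, made from both replicates. The second is a candidate list called on the pooled alignments of both replicates, and the third is a candidate list for each replicate alone. Candidate lists mix peaks with background and served as input to the reproducibility step. They were called with a control alignment that was not used here. The aligner, the peak caller and the threshold were not given in the sources used here. The deposited signal value of each peak is the authors' own number, on a scale not given in the sources used here, and it served to rank and describe peaks within a list. The deposited −log10 q column held 1 constant value in the reproducible list, so it ranked no peak there. Read totals were not used here, so the depth of each sample is unknown. Intervals on shares are exact Clopper-Pearson 95% intervals, and they cover counting error only. All p-values describe positions along the genome in these 2 samples, not the spread between further worms.

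Peaks on ce11 were set against the Ensembl release 115 annotation of the same assembly and its sequence. Every ce11 entry lay inside the reference chromosomes. The ce10 lists entered only counts, overlaps and correlations. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are 1-based.

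A promoter window ran from 500 bp upstream to 100 bp downstream of an annotated gene start, on the gene's strand, and a gene had a peak when a summit lay in its window. Promoter and annotation shares were compared with 10000 circular shifts of the peaks within chromosomes, with Benjamini-Hochberg adjustment over the annotation classes. Each summit counted in a single class, in the order promoter window, 5′ UTR, coding exon, 3′ UTR, noncoding exon, intron, intergenic. The smallest p these shifts can give is 0.0001 one-sided and 0.0002 two-sided. Replicates were compared by the overlap, by at least 1 bp, of the 748 strongest entries of each, a length equal to that of the reproducible list. Counts per chromosome were compared with the shares of promoter windows by 100000 multinomial draws, whose smallest p is 1e-05. Arms were the first and last of 3 equal parts of each autosome. A total of 31 gene lists were tested with the two-sided Fisher's exact test and Benjamini-Hochberg adjustment. Protein-coding lists were compared with other protein-coding genes, and the tRNA, snoRNA, snRNA, microRNA and heterochronic lists with all other genes of any biotype. Genes that share a peak between divergent starts are both counted. List members were taken by gene name or biotype, so a list's label is not evidence of where a member acts.

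A total of 27 short sequence words were counted on both strands in the 100 bp around each summit. They were compared with the mean of the windows centred 400 bp to either side by an exact two-sided sign test with Benjamini-Hochberg adjustment. Simulated data showed that this test is off centre, because a rare word is more often found in at least 1 of 2 flanks than in 1 centre. On peaks shifted to unchanged positions it called 271 of 540 words, against 1 of 540 with 1 randomly drawn flank per peak. The one-flank test was therefore added after the data were examined, and a word is described as higher or lower only where both tests passed. A word planted in 20% of windows was called by the one-flank test in 20 of 20 runs. A simulated promoter share set to 60% came back as 60.03%, and 1 of 20 sets of shifted peaks passed the threshold for the promoter share. A raised gene list was called in 20 of 20 runs, with 2 of 600 calls of other lists. The raised list was that of ribosomal protein genes with a large planted excess, so these runs do not cover smaller lists or weaker effects. Other simulated peaks fell on independently drawn genes, so clustering of the real peaks was not simulated.

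The gene lists, the words, the tests and the rule for named genes were fixed before the data were examined. The rule names ceh-82, the genes whose window holds one of the 15 strongest peaks in any window (noncoding genes only where no protein-coding window holds the peak), 4 members of each list past the threshold, up to 2 members of each other list, and up to 10 homeobox genes with a peak. The members are those of highest signal. Some chemoreceptor members that the rule names are not reported here. Alternatives covered the window size, the peak position, a signal threshold at the list's median, each replicate's own list, the other build, the test of the lists, the background of the words and the flank around ceh-82. Alternatives added after the data were examined left out piRNA genes or chromosome X, changed the expected chromosome shares, or drew 1 flank per peak.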

Results

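Binding of eGFP-tagged CEH-82, a homeodomain protein, was mapped by ChIP-seq in whole L3 larvae in 2 biological replicates. The question was where along the genome the tagged protein was recovered. The reproducible list held 748 peaks on ce11, with a median signal value of 38.6 and a range from 26.9 to 330. The commonest width was 340 bp, shared by 91.4% of the peaks. The candidate lists held 30000 entries for the pooled samples, 30000 for replicate 1 and 22611 for replicate 2. The depth of the libraries is unknown.

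Most reproducible peaks were among the strongest entries of each replicate, in a list that was itself selected for reproducibility between them. Of the 748 reproducible peaks, 646 (86.4%, 95% interval 83.7 to 88.7) lay among the 748 strongest entries of replicate 1. Among those of replicate 2 were 491 (65.6%, 62.1 to 69.0). The replicates' own top lists shared 56.4% of entries (422 of 748, counted in replicate 2), against a mean of 0.513% after circular shifts (permutation p = 0.0001, the smallest the shifts can give). Random entries of the whole candidate list of replicate 2 gave 3.44%. At the 734 peaks with a value in both replicates, the median signal was 28.9 in replicate 1 and 11.1 in replicate 2. Across these peaks, which are not independent replicates, Spearman's rho was 0.430 (bootstrap 95% interval 0.360 to 0.496). Pearson's r of the log2 signal was 0.569, and of the untransformed signal 0.820. The promoter of rpl-3, which encodes a protein of the large ribosomal subunit, had a signal of 224 in replicate 1 and 84.2 in replicate 2.

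**Figure D1:**
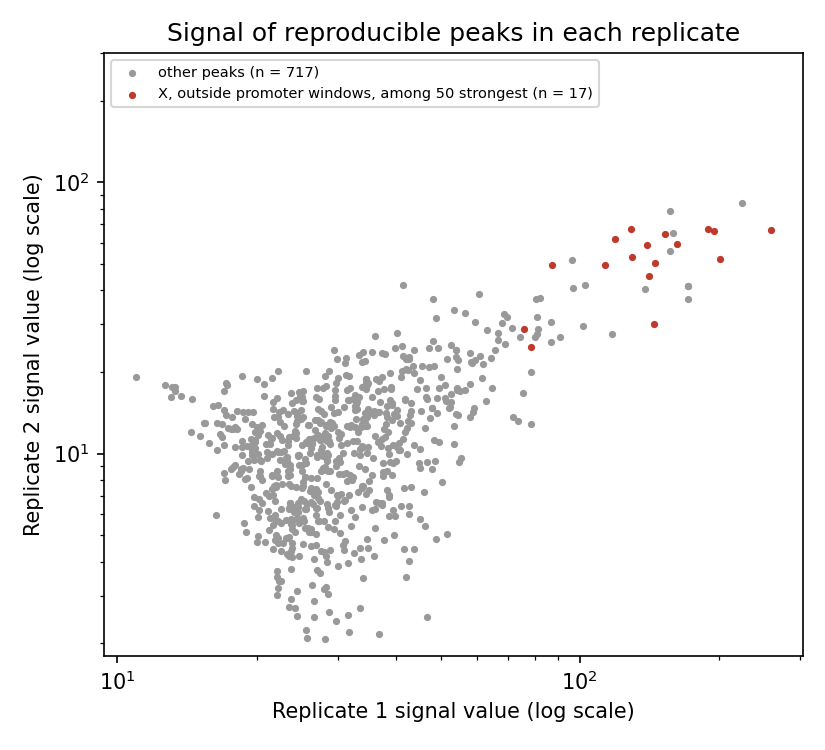
Signal value of each reproducible peak in replicate 1 (x axis) and replicate 2 (y axis), both on log scales, for the 734 peaks with a value in both. Red points are the 17 peaks on X outside promoter windows among the 50 strongest, and they lie at the high end in both replicates.

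The gene that encodes the target was itself without a reproducible peak. ceh-82 (WBGene00018433) lies on chromosome II from 1732232 to 1733291 on the plus strand of ce11, and the nearest reproducible peak was 412 kb away. Within 20 kb of the gene, 0 reproducible peaks were found, where shifts gave a mean of 0.291. With so few expected, the test for as many peaks cannot be informative (permutation p = 1). The same region held 2 entries of the pooled candidate list, against 12.1 after shifts. Each replicate's candidate list held 4 entries there, against 11.9 for replicate 1 and 9.15 for replicate 2. For as few entries, the shifts gave permutation p = 0.0550 (pooled), 0.127 (replicate 1) and 0.174 (replicate 2), so no list passed. With 40 kb flanks the permutation p was 0.0168, 0.0893 and 0.0328 in that order. With 10 kb flanks the lowest was 0.193. These values are not adjusted. The tagged gene was carried on a transgene per the strain label, and extra copies of the locus can raise the signal here. Such copies were not separated from the chromosomal gene, so neither the entries nor their number can be assigned to it.

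Peaks lay mostly at gene starts. The summit was in a promoter window for 519 of 748 peaks (69.4%, 65.9 to 72.7), against a mean of 19.3% and a maximum of 26.2% after shifts (permutation p = 0.0001). Coding exons held 1.47% of summits against 21.4% after shifts, and introns held 8.56% against 31.5% (permutation test, adjusted p = 4.67e-04 for each). Intergenic sequence held 17.1% against 22.3% (permutation test, adjusted p = 0.00140). Promoter windows took priority over the other classes, so the excess there leaves less room for each of them. These lower shares alone therefore do not show avoidance. Outside windows, 128 summits were intergenic, 64 in introns and 11 in coding exons, while shifts gave introns a larger share than intergenic sequence. The shares in 5′ UTRs (1.07%), 3′ UTRs (1.60%) and noncoding exons (0.802%) did not pass the threshold, though 3′ UTRs did at the stricter signal threshold (0.535%, permutation test, adjusted p = 0.0101). With replicate 2's own list alone, intergenic sequence no longer passed (19.5%, permutation test, adjusted p = 0.109), and with replicate 1's own list noncoding exons passed (0.668%, permutation test, adjusted p = 0.0227). The coding exon share was 2.94% with replicate 2's own list and passed there too.

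**Figure D2:**
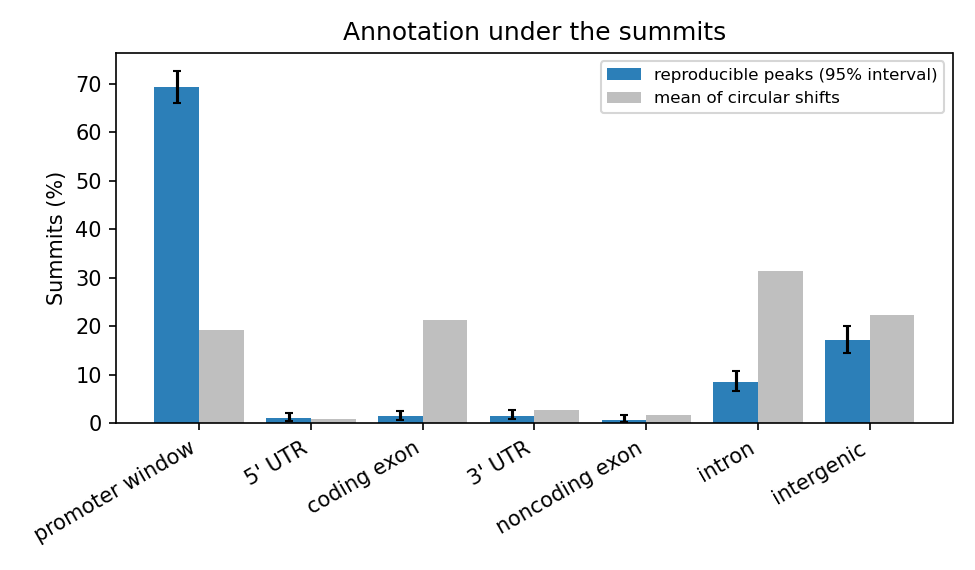
Share of the 748 summits in each annotation class (blue, with exact 95% intervals) beside the mean of the circular shifts (grey), in percent. Promoter windows hold 69.4% of summits against 19.3% after shifts.

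The 15 strongest peaks in promoter windows included 4 at genes of the large ribosomal subunit. The peak at rpl-3 (III, 3867439 to 3867703) had a pooled signal of 306. Those at rpl-35 (III, 7854563 to 7854805), at rpl-20 and the divergent Y17G9B.5 (IV, 4749958 to 4750186), and at rpl-15 and K11H12.8 (IV, 654826 to 655033) had signals of 214, 209 and 180. These rpl genes encode proteins of the large ribosomal subunit. The promoter of cdc-48.1, an AAA ATPase that extracts ubiquitinated proteins, had a signal of 239, and that of tasp-1 had 223. cox-5A, a subunit of cytochrome c oxidase, had 146. A shared peak between mig-5, a Dishevelled protein of Wnt signalling, and cct-1, a subunit of the TRiC chaperonin, had 138. sec-61.G, of the protein translocation channel, had 135, eelo-2 had 118.9 and ints-4, of the Integrator complex, had 118.6. The noncoding gene C18A11.13 on X had 211. Small RNA genes among the strongest were the spliced leader genes sls-2.1 (143) and sls-2.4 (136, a peak also in the window of R12E2.18) and the snRNA gene R07E5.16 (118).

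By gene list, peaks were above other genes at ribosomal, translation, chaperone, respiratory chain, cell cycle, tRNA, snoRNA and snRNA genes. Of 80 cytosolic ribosomal protein genes, 31 had a peak (38.8%, 28.1 to 50.3), which was 17.3-fold the share of other protein-coding genes (Fisher's exact test, adjusted p = 1.50e-28). The fold was 7.34 with the window from 250 bp upstream to 50 bp downstream and 10.9 with the nearest gene start, and it ranged from 7.34 to 22.5 over the alternatives. Translation factors had a peak at 8 of 40 genes (8.50-fold, exact test, adjusted p = 2.03e-05), with iff-2 (97.9), eef-2 (66.8), eef-1G (56.6) and eif-3.C (51.4) the highest in signal. At the stricter signal threshold their fold was 13.5. Heat shock proteins and chaperones had one at 11 of 60 genes (7.83-fold, exact test, adjusted p = 9.50e-07), with cct-8 (74.3), hsp-1 (71.7) and hsp-3 (58.4) next to cct-1. This call was lost when peaks were given to the nearest gene start within 2 kb (2.47-fold, exact test, adjusted p = 0.293). Of 52 genes of oxidative phosphorylation, 8 had a peak (6.53-fold, exact test, adjusted p = 1.32e-04), and atp-1 (69.5), nduf-11 (57.1) and cox-5B (46.7) followed cox-5A. Of 80 cell cycle genes, 8 had a peak (4.24-fold, exact test, adjusted p = 0.00221), with efl-1 (62.7), an E2F factor, knl-3 (49.8), of the kinetochore, and pcn-1 (45.8), the replication clamp, after cdc-48.1. The cell cycle call was lost at the stricter signal threshold (3.81-fold, exact test, adjusted p = 0.0752) and with replicate 2's own list (2.97-fold, 0.0708).

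Windows of tRNA, snoRNA or snRNA genes held 14.97% of the peaks, and 18 of these peaks also lay in a protein-coding window. A peak was found at 69 of 612 tRNA genes (11.3%, 7.53-fold the share of other genes, exact test, adjusted p = 3.34e-35). These were 61 peaks, of which 40 were on X. The share of tRNA genes that lie on X was not set beside this count, so no preference for X can be read from it. The highest were at WBGene00023111 and its divergent neighbour WBGene00023110 (signal 84.0), WBGene00014486 (76.1) and WBGene00014296 (74.6), all on X. Of 346 snoRNA genes, 44 had a peak (12.7%, 8.24-fold, exact test, adjusted p = 6.63e-25), with T03F7.8 (113), F54E7.10 (111.5) and the neighbours C51F7.4 and C51F7.3 (101.1) the highest. Of 129 snRNA genes, 10 had a peak (7.75%, 4.82-fold, exact test, adjusted p = 2.03e-04), and T11F9.15 (76.3) followed those named above. Among the genes compared with were 15363 piRNA genes, of which 16 had a peak. Without them the folds were 5.15 for tRNA, 5.65 for snoRNA and 3.31 for snRNA genes, and without chromosome X the fold for tRNA genes was 4.40. All 3 lists passed in each of the 12 alternatives tried, though leaving out the region around ceh-82 removed no peak.

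Chemoreceptor genes, which encode the sensory receptors of chemosensory neurons, were below other genes. A peak was found at 3 of 1365 (0.220%, 0.0453 to 0.641), 0.0863-fold the share of other protein-coding genes (exact test, adjusted p = 1.63e-10). The highest in signal was sri-5 (55.3). The fold was 0.0323 with replicate 2's own list and 0.132 with the smaller window. No other list passed. Homeobox genes, the family of CEH-82 itself, had a peak at 0 of 97 genes (upper bound 3.73%, exact test, adjusted p = 0.291). Collagens had one at 0 of 178 (upper bound 2.05%, exact test, adjusted p = 0.0674). Body wall muscle (0 of 39), intestinal (0 of 62), epidermal (0 of 17), ciliary (0 of 68), neuropeptide (0 of 144) and neurotransmission genes (0 of 133) also had none, and none of these differed from other genes past the threshold. Even this lowest possible count gave an unadjusted p of 0.0529 (neuropeptide genes, exact test) or more in these lists and in homeobox genes (0.178). A depletion there could therefore not have been called.

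Splicing proteins had a peak at 4 of 41 genes, snr-4 (76.3) and prp-40 (41.7) among them, just short of the threshold (exact test, adjusted p = 0.0502). These 4 genes held 3 distinct peaks. The snr-4 peak is the one named above for the snRNA gene T11F9.15, with a summit at -22 bp from that start and -373 bp from snr-4. With replicate 2's own list the splicing proteins passed (6.99-fold, exact test, adjusted p = 8.10e-04), while with replicate 1's they did not (2.12-fold, 0.379). They also passed with the wider window (exact test, adjusted p = 0.0250) and with whole intervals (0.0145). With replicate 2's own list the vacuolar proton pump (exact test, adjusted p = 0.0266) and pan-neuronal genes (0.0257) passed, and with replicate 1's own list the vacuolar proton pump passed (exact test, adjusted p = 0.0370). The proteasome list had 3 of 33 (rpn-3 at 49.6 and rpn-11 at 39.3), histones 4 of 80 (his-37 at 88.4 and his-24 at 34.3) and the vacuolar proton pump 2 of 21 (vha-12 at 40.7 and vha-8 at 32.8). Nuclear hormone receptors had 2 of 274 (nhr-47 at 46.6 and nhr-1 at 29.6), basic helix-loop-helix factors 1 of 35 (hlh-11 at 51.5) and molting genes 1 of 109 (nas-10 at 43.6). The pharyngeal list had 3 of 94 (pqn-70 at 50.6 and pqn-51 at 43.6), the pan-neuronal list 2 of 38 (snb-1 at 65.0 and ida-1 at 31.2) and the germline list 2 of 105 (puf-9 at 101.2 and mes-2 at 38.8). The Wnt list had 1 of 28, mig-5. The insulin and stress list had 2 of 75 (xbp-1 at 37.2 and gst-27 at 34.2), and heterochronic genes had 1 of 13 (lin-66 at 27.1). The name pattern for microRNA genes took only 8 of the 261 genes of that biotype, with a peak at mir-1831 (38.1). Of all 261, 6 had a peak.

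**Figure D3:**
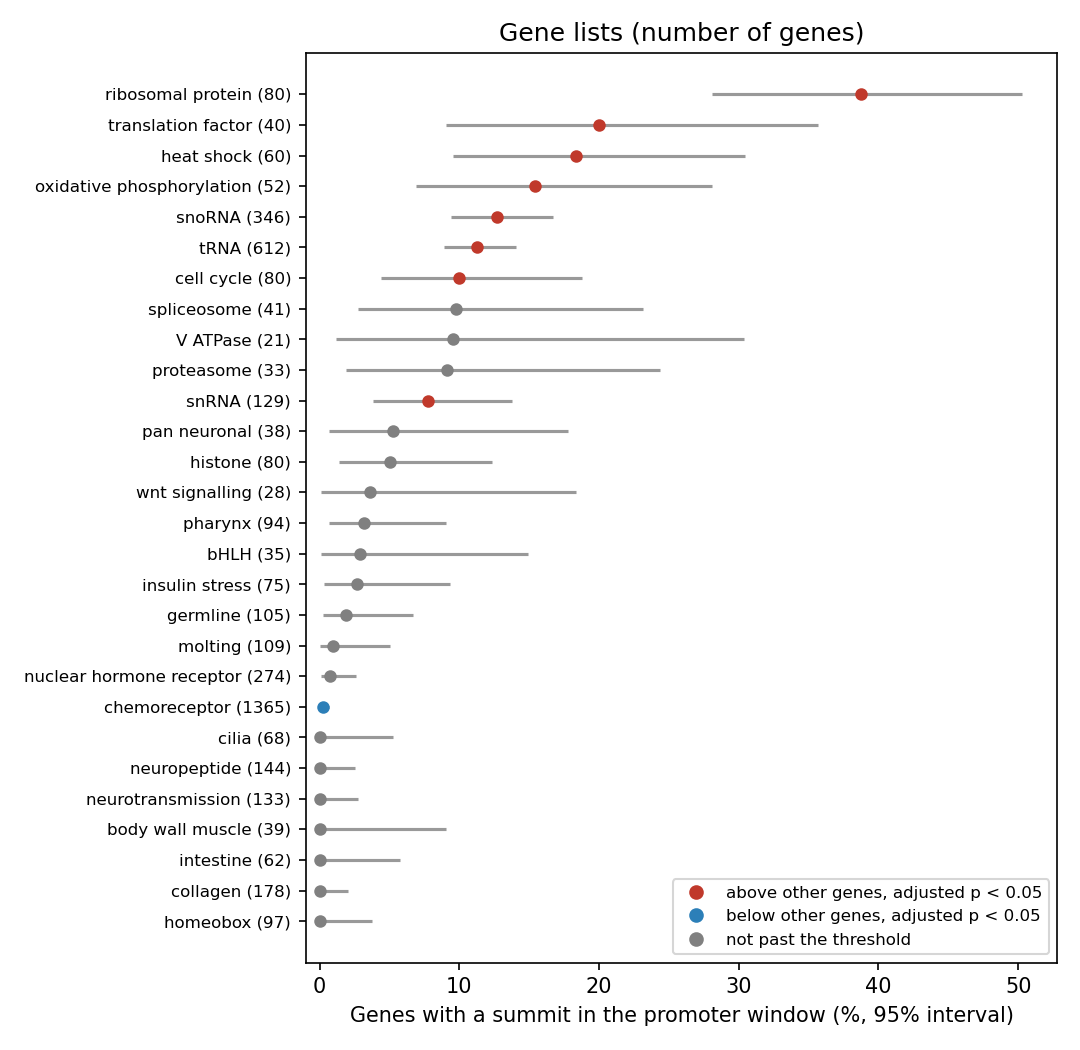
Share of genes with a summit in the promoter window, in percent, for the lists of at least 20 genes (number of genes in brackets, bars are exact 95% intervals). Ribosomal protein genes stand highest at 38.8%, and chemoreceptor genes (blue) lie at 0.220%.

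Chromosomes III and I held more peaks than their promoter windows predicted and V held fewer. The size of the excess on X depended on the expectation. With piRNA genes left out of the expectation, a choice made after the data were examined, III held 145 peaks (1.62 times the expected number), I held 130 (1.33 times), X 156 (1.12 times) and V 0.555 times the expected number. The shares of III (19.4%, 16.6 to 22.4) and I (17.4%, 14.7 to 20.3) lay above the expected 11.99% and 13.02%, and that of V (13.5%, 11.1 to 16.2) below the expected 24.3%. The chi-square was 85.4 (permutation p = 1e-05, the smallest the draws can give). With all genes in the expectation it was 359 (permutation p = 1e-05), because 15363 piRNA genes raise the expected number on IV to 314 against 107 observed. Chromosome II changed direction between the expectations, from 1.31 times with all genes to 0.897 times without piRNA genes. X held 1.62 times the expected number with all genes, 1.53 times with protein-coding genes and 1.18 times by chromosome length. The 95% interval of its share (20.9%) lay above the expected 12.8%, 13.7% and 17.7% in that order. That interval held the 18.6% expected without piRNA genes. On autosomes, 62.3% of peaks lay in the arms (58.3 to 66.2), against 61.6% of genes without piRNA genes and 71.7% of all genes.

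The strongest peak of all and most of the 20 strongest were on X and away from gene starts, a split chosen after their values were seen. Of the 20 strongest peaks, 14 were on X, and 13 of these lay outside promoter windows, against 0 autosomal peaks outside windows. Of the 50 strongest, 20 were on X with 17 outside windows, against 1 on autosomes. The 50 strongest entries of each replicate's own list also held 17 such peaks on X, against 3 on autosomes in replicate 1 and 6 in replicate 2. The 17 strong peaks comprised 14 intergenic sites, 2 in introns and 1 in a coding exon, at a median of 1794 bp from the nearest gene start. The strongest, intergenic at X 11094008 to 11094377, had a signal of 330 (259 in replicate 1 and 67.0 in replicate 2). The next of these 17 were intergenic at X 14525686 to 14526096 (259), intronic at X 2996928 to 2997300 (253) and intergenic at X 4209123 to 4209411 (253).

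**Figure D4:**
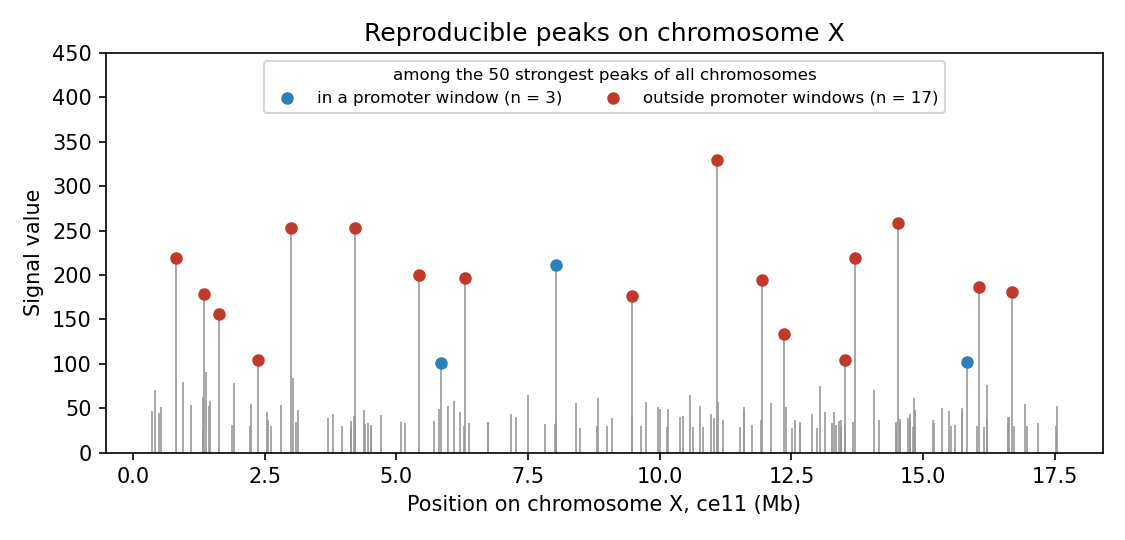
Signal value of the 156 reproducible peaks on X (y axis) by position in Mb on ce11 (x axis), with points on those among the 50 strongest of all chromosomes. The 17 red points, outside promoter windows, are spread along the chromosome, and the highest has a signal of 330.

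Summits were richer in G and C than their flanks and held 5 of the 27 words more often. The mean GC content was 48.5% ± 7.93 (SD over 748 peaks) at summits and 36.4% in flanks. CTGCGTC was present in 13.4% of summit windows against 0.334% of flanks (exact sign test, adjusted p = 1.16e-26), GTCTC in 39.4% against 11.97% (4.75e-21) and TGCGC in 34.8% against 6.35% (7.02e-30). The repeat GAGAGAG was present in 13.8% against 1.47% (9.23e-15) and GCGCGC in 11.1% against 0.535% (2.27e-16). These 5 words were also higher than in promoter windows of genes without a peak matched on distance and GC content by presence (CTGCGTC 11.6% against 3.85%, Fisher's exact test, adjusted p = 3.36e-05). For GAGAGAG this held for presence (9.44% against 5.01%, Fisher's exact test, adjusted p = 0.0239), while its mean copies were 1.05 times those of matched promoters, against 15.3 times those of flanks.

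The homeodomain core TAAT and 3 longer words that hold it were less frequent at summits than in flanks. TAAT was present in 33.2% of summit windows against 63.2% of flanks (exact sign test, adjusted p = 1.85e-55), and TAATTA, TAATTG and TTAATTG were also lower. TAATCC and TGATTAAT, which hold TAAT too, did not pass both tests. The GATA word TGATAA, the trans-splice acceptor TTTCAG, AAATTG and the run of T were lower as well, 8 words in all. Against GC-matched promoter windows the difference in TAAT shrank to 30.8% against 37.4% and no longer passed (Fisher's exact test, adjusted p = 0.0828), and 6 other words lost their calls too. Of these, TAATTA (ratio of mean copies 0.5, in 4 against 8 windows), TGATAA (0.528, 18 against 31) and TAATTG (0.609, 13 against 21) kept ratios below 1, TTAATTG (1) and AAATTG (1.06) did not, and the run of T was in 3.85% of both sets. CAAGTG, a word of NK-2 type homeodomain proteins, was present in 8.42% of summit windows against 3.28% of flanks. It missed the threshold in the planned test (exact sign test, adjusted p = 0.119). It also missed it in 6 of 8 alternatives (up to 0.786), which all reuse that test and share its lean against rare words. It passed in the alternatives that replace the test, with 1 flank per peak (exact sign test, adjusted p = 9.17e-05) and against GC-matched promoters (9.63% against 4.82%, Fisher's exact test, adjusted p = 0.0169). Of the 8 words TTTCAG alone still passed as lower (4.62% against 9.06%, Fisher's exact test, adjusted p = 0.0239). CACCTG (1.73% against 5.20%, Fisher's exact test, adjusted p = 0.0169) and GGTCAA (1.73% against 4.82%, 0.0239) were also below matched promoters, but neither passed with 1 flank per peak. The planned test alone called 20 words, 5 higher and 15 lower, but it favours lower calls for rare words, and 7 of its lower calls failed with 1 flank per peak.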

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

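The one-flank test, the expectations without piRNA genes and the settings without chromosome X were chosen after the data were examined. The promoter share stayed above the shifts in all 8 alternatives, between 55.3% and 77.1%. The overlap of the replicates' top lists passed in all 5 alternatives. The chi-square over chromosomes passed in all 8 alternatives, and chromosome II alone changed direction with the expectation. The number of lists past the threshold ranged from 8 to 11 around 9, and 7 of the 9 passed in all 12 alternatives. Leaving out the region around ceh-82 removed no peak, so that alternative could not differ. Leaving out piRNA genes could not change the folds of protein-coding lists. Heat shock genes failed in 1 (adjusted p from 3.45e-07 to 0.293) and cell cycle genes in 2 (0.00221 to 0.0752). Splicing, proteasome, vacuolar proton pump, pan-neuronal and heterochronic genes passed in at least 1 alternative.

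The reproducible count was 374 at the stricter signal threshold, which keeps the upper part by construction, and 497 to 652 entries of a single replicate's own top list overlapped the reproducible list, which itself needs both replicates. Pearson's r rose to 0.820 on untransformed signal, where the strongest peaks weigh most. The candidate lists of replicate 1 and replicate 2 each held 4 entries near ceh-82. These lists mix peaks with background, and which of the 2 these entries are was not tested. The planned test called 20 words, and Fisher's exact test of 519 promoter summits against GC-matched promoters called 9, a setting that differs in test, peaks and background. Some words that the planned test called lower were in more summit windows than matched windows there. Ratios of mean copies were 1 for TTAATTG, 1.06 for AAATTG and 1.94 for ATCGAT, and none of these passed. With 1 flank per peak, more peaks had a higher than a lower count at the summit for TGACAG (1.07), ATCGAT (1.52) and GGTCAA (1.12), and none passed. The planned ratios of TGACAG and ATCGAT were already above 1 (1.07 and 1.28). Both words were also in more summit windows than flanks (3.74% against 3.54% and 4.81% against 4.14%), so only the sign test's direction changed. TGACTCA had a ratio of 0.714 to 2.33 when a replicate was left out. The ratio of CTGCGTC fell from 43.6 to 15.3 with replicate 2's own list and 27.25 with replicate 1's. That of GCGCGC fell from 27 to 9.67 and 21.6, and both words stayed higher in the planned test. The cause of the other changes was not tested.

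No paired analysis was possible because there is 1 group. Unknown depth leaves open whether the lower signal of replicate 2 reflects fewer reads.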

Other observations

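The tests of the recruitment word, of overlap between the replicates' own lists, of TAAT against matched promoters, of base composition and of muscle and collagen genes were chosen after the results were seen. The criterion for repeated sequence was written before its result was seen.

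At tRNA genes the median summit was at -19 bp from the gene start (69 pairs of gene and peak), at snoRNA genes at -42 bp (44 pairs) and at snRNA genes at 10.5 bp (10 pairs). At ribosomal protein genes it was at -265 bp (31 pairs, quartiles -330.5 to -248). The word CTGCGTC was present at 33 of 167 autosomal peaks outside windows (19.8%, 14.01 to 26.6), 55 of 388 peaks in other promoter windows (14.2%, 10.9 to 18.05), 3 of 61 in tRNA windows and 0 of 30 in ribosomal protein windows (upper bound 11.6%). The repeat GAGAGAG was at 46 of the 167 autosomal peaks outside windows (27.5%, 20.9 to 35.0) and 1 of 30 in ribosomal protein windows. Differences between these kinds were not tested.

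The strong X peaks outside promoter windows share a word with recruitment sites of the dosage compensation complex, the condensin-like assembly that lowers expression of both X chromosomes in hermaphrodites. The 12-base word TCGCGCAGGGAG, known from such sites, lay within 100 bp of the summit, with at most 2 mismatches, in 13 of 17 peaks against 2 of 34 flank windows 600 bp away (Fisher's exact test, p = 4.26e-07). With at most 1 mismatch it was in 10 of 17 against 0 of 34, and of all such sites in the genome, merged within 500 bp, 12 of 27 on X had a reproducible peak within 100 bp against 0 of 37 on autosomes (Fisher's exact p = 5.29e-06), while with at most 2 mismatches it was 19 of 265 on X against 6 of 1320 (Fisher's exact p = 6.73e-11). The reference was searched for exact copies of 50-base pieces laid end to end within 100 bp of each summit, and 0 of 17 peaks held a repeated piece. That argues against exact repeats, while inexact copies were not searched for and stay open. A single replicate is argued against, since 16 of the 17 such entries among the 50 strongest of replicate 1's own list overlapped one of replicate 2's. Those lists were not selected for reproducibility. Recovery at recruitment sites may therefore be a candidate explanation, as a hypothesis found and tested on the same data, while recovery that does not depend on the tagged protein and copies missing from the reference stay open, because neither a control library nor another target was analysed here.

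Promoter peaks of this homeodomain protein held few TAAT words and lay often at ribosomal protein, tRNA and snoRNA genes. Of the gap in TAAT to promoter windows matched on distance alone (30.8% against 60.3%), 22.2% (2.70 to 41.7, with the full gap taken as fixed) was left when GC was matched too. GC was matched in the same 100 bp in which TAAT was counted, and TAAT holds no G or C. Such matching removes TAAT whatever the cause, so it cannot decide whether base composition explains the shortage. The share with TAAT minus that of GC-matched promoters was -6.55 percentage points (-12.3 to -0.797) over these 519 promoter peaks, so no excess of TAAT was found. Matching GC in the counted window leans against finding an excess, so this difference cannot decide whether TAAT is the main route. Without GC matching there was no excess either (30.8% against 60.3%). TAAT was present at 160 of the 519 summits, so it was absent from the 100 bp around most of them, while single sites stay open. The interval is not adjusted over the words, and mean GC was 49.2% at summits against 47.9% in the matches. Other homeodomain words are not covered, and CAAGTG was above matched promoters (9.63% against 4.82%). Signal at heavily transcribed genes of any tissue cannot be told apart from specific binding: 0 of 217 muscle and collagen genes had a peak (upper bound 1.69%, against a lower bound of 28.1% for ribosomal protein genes), but transcription in these worms was not analysed here.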
